A study of Mus musculus with 6 samples.

How the data were processed

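Chromatin immunoprecipitation followed by promoter microarray (ChIP-chip) was run on mouse C57BL/6J keratinocytes, the main cell type of the epidermis. The cells were kept for 4 days in high-calcium medium after they had become confluent, a treatment that starts their terminal differentiation. Per the labels' protocols, proteins were crosslinked to DNA with 2 mM DSG, a protein-to-protein crosslinker, and 1% formaldehyde, chromatin was sheared to 500 bp, and DNA was recovered with an antibody to Plakoglobin or to β-catenin. There were 6 arrays, 3 per antibody, numbered 1 to 3 within each. Each array carried 2 channels, the ChIP DNA labelled with Cy5 and the total input DNA labelled with Cy3, so a positive log2 ratio, before centring, is ChIP above input. Arrays with a mock antibody, or from cells without either protein, were not analysed here, so input was the background for every value.

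The deposited tables hold a log2 ratio of ChIP over input for each promoter sequence, the mean, median and standard deviation over its probes, per the file headers. The normalization of the probe values before that step is not given in the sources used here. The mean tables and the table of the whole series were identical (largest difference 0), so using either gives the same values. Of 26275 promoter sequences, 75 had no value, which left 26200. They carry 22505 accessions, of which 586 have more than 1 sequence (4281 sequences). The deposited peak lists come from NimbleGen's peak algorithm, per the file headers, with 1 list per array and no pooling of arrays. Each peak carries a score, which is the authors' value and whose scale is not given in the sources used here, and a false discovery rate, a q-value, of up to about 0.2, per the file headers. The authors list a peak under every nearby transcription start site, with its distance, so 1 peak can stand under several genes. The genome build of the coordinates is not given in the sources used here, so positions are printed as deposited and no sequence was looked up.

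Gene names were updated through a RefSeq gene table of assembly GRCm38.p6, used for names only. By accession 12527 sequences were named, by symbol 3205 and by synonym 2371, 1012 kept the name in the files, and 7085 stayed unnamed. Names used for gene lists were taken without regard to whether a promoter had a peak.

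Each array's log2 ratios were centred on their median. A value of 0 is therefore the array's median promoter, and tests over input compare a group mean with that median. A group-means model was fitted to all 6 arrays with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a trend, two-sided tests). The trend lets the modelled spread follow a promoter's mean log2 ratio, since no intensities entered the fit. Each group mean was tested against 0 and against the other, with a Benjamini-Hochberg threshold of 0.05 over all 26200 promoters. Promoters with peaks of an antibody in at least 2 of 3 arrays were counted per accession. The overlap between antibodies was tested with a one-sided Fisher's exact test, and with 10000 random shifts of the promoter order along the genome, which keep neighbouring promoters together. The fixed gene lists were Wnt targets, Wnt pathway components, desmosome, adherens and tight junction, terminal differentiation, basal keratinocyte, keratin genes, proliferation, cell cycle exit, Myc targets, Notch pathway, hair follicle stem cell, ribosomal protein, respiratory complex I, histone genes, Hox genes, olfactory receptors, vomeronasal receptors, and markers of fibroblasts, melanocytes and immune cells. Each list was tested with camera at a preset correlation, Benjamini-Hochberg adjusted within each contrast, and again with an estimated correlation. A gene with several promoters was represented by the one with the highest mean over all arrays, which raises the share of genes above 0 (62.0% of 15647 named genes with Plakoglobin and 57.0% with β-catenin). Unnamed promoters stayed in the background of the list tests unmerged (25003 promoters in all), which may favour higher ranks for lists of named genes. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used for the rest.

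The samples, tests, gene lists, most alternatives and the rule for named genes were set before the data were examined. The rule takes, per antibody, the 10 highest promoters past the threshold and above 0 in all 3 arrays, and for the difference between antibodies the 10 largest per direction past the threshold. Where fewer than 5 pass in a direction, it takes the 5 with the smallest p, as not passing. It adds the 10 highest promoters with peaks of both proteins in at least 2 of 3 arrays, 17 fixed genes (of which 14 have a named promoter; Lef1, Dsc3 and Krt1 were not analysed here), and the 4 members of each list with the smallest p for the difference. Genes named outside the rule are said to have been chosen after their values were seen.

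The labels do not say that arrays with the same number share a culture, but the file headers call both arrays of a number the same experiment. Deviations from the group means correlated at 0.203, 0.235 and 0.218 within the pairs of equal number, so the numbers were taken to pair the arrays. The main fit and its SEs ignore this pairing, and a fit with the number as a block was run as an alternative. Nothing in the labels says that arrays of one antibody came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision: the median SE of a difference between antibodies was 0.29 on the log2 scale.

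The model was tested on simulated data made from these 6 arrays with 50 promoters changed at each size. The simulated arrays had independent noise, without the pairing by number. Simulated promoters also had a mean of 0 before the planted change, so the link between mean ratio and spread in the real fit was not kept. The recovery may therefore be too high for promoters with a high mean ratio, such as Bmt2, where the SE of the difference was 2.41. For the difference between antibodies over 26200 promoters the model recovered 2% of changes of log2 size 1, 38% of size 2, 72% of size 3 and 86% of size 4, with 5 false calls. Among the 1 in 4 promoters with the lowest spread it recovered 4% at size 1 and 84% at size 2, with 12 false calls. The overlap test gave p under 0.05 for 2 of 40 simulated independent pairs. The alternatives covered centring, scaling between arrays, the variance model, array weights, promoters with 1 probe, the threshold, the peak threshold and overlap rule, the set test and leaving out each array.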

Results

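Plakoglobin (γ-catenin, gene Jup) and β-catenin (gene Ctnnb1) are closely related proteins of cell-cell junctions that can also act with TCF/LEF transcription factors in the nucleus. Their occupancy of promoters was measured in differentiating mouse keratinocytes on 3 arrays per antibody, as the log2 ratio of ChIP DNA over input DNA at 26200 promoter sequences. Values are median-centred log2 ratios, given as mean ± SD over the 3 arrays of an antibody. The median ratio before centring was 0.23, 0.45 and 0.19 on Plakoglobin arrays 1 to 3 and 0.15, 0.45 and 0.18 on β-catenin arrays 1 to 3. The authors' lists held 2524, 2684 and 1739 peaks for Plakoglobin and 436, 330 and 1958 for β-catenin. The mean was 2316 ± 506 peaks for Plakoglobin and 908 ± 911 for β-catenin, with overlapping single arrays (two-sided exact permutation test, p = 0.2), and 3 against 3 arrays cannot give a p below 0.1, so this test could not have called a difference.

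Arrays of the same antibody resembled each other less than arrays of the same number. Spearman correlations over promoters were 0.034, 0.288 and -0.007 among the Plakoglobin arrays and 0.14, 0.135 and 0.069 among the β-catenin arrays, against 0.347, 0.376 and 0.414 between the Plakoglobin and β-catenin arrays of numbers 1, 2 and 3. Promoters are not independent replicates, so these correlations describe the arrays and carry no p-value.

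**Figure D1:**
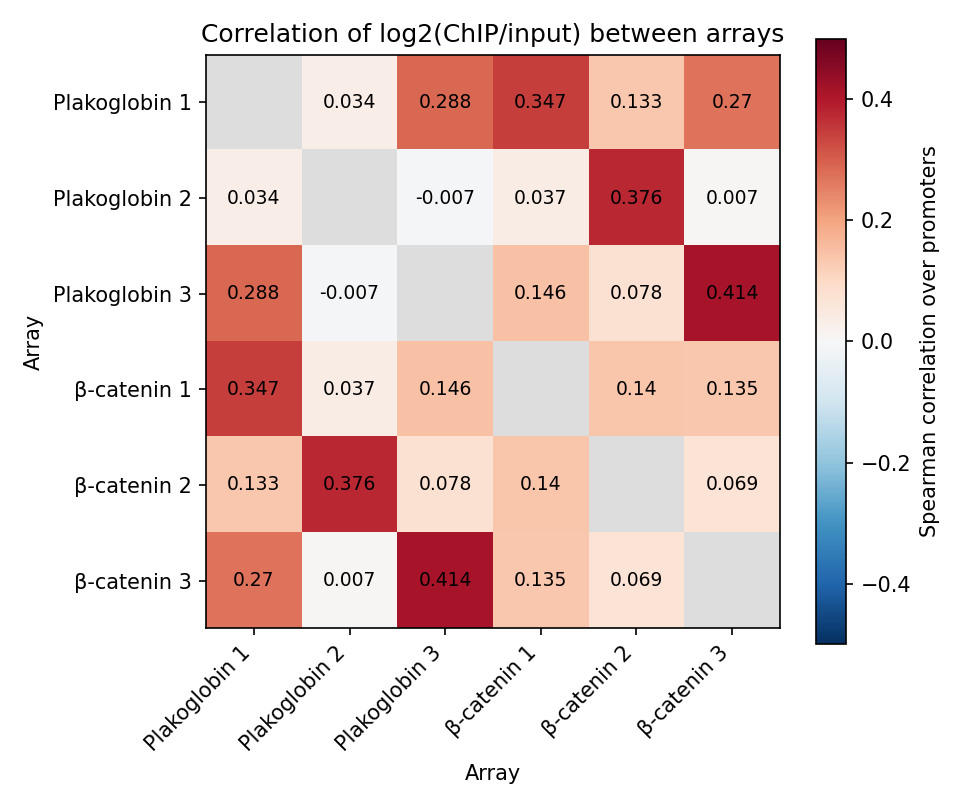
Spearman correlation of the log2 ratio of ChIP over input between each pair of the 6 arrays, over promoter sequences, with the antibody and number of each array on both axes. The pairs with the same number reach 0.347, 0.376 and 0.414, and the highest value within an antibody is 0.288.

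The first comparison asks which promoters Plakoglobin occupied above input. At the promoter of Jup itself the ratio was 0.78 ± 0.96, above 0 in 3 of 3 arrays, with a peak in 1. Ccnd1, which encodes the G1 cyclin D1, had 0.57 ± 0.68 and a peak in 1 array, and Krt5, a keratin of basal keratinocytes, had 0.49 ± 1.31 and a peak in 1. Myc, the proliferation-promoting transcription factor, had 0.20 ± 0.16 and was above 0 in 3 of 3 arrays, without a peak. Axin2, a widely used Wnt target, had -0.06 ± 0.01, and the differentiation genes Krt10 and Ivl (involucrin) had -0.17 ± 0.09 and -0.18 ± 0.39. The desmosomal cadherin genes Dsc2 and Dsg3 had -0.11 ± 0.29 and 0.30 ± 1.28.

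No promoter passed the threshold for Plakoglobin over input in limma (0 of 26200, lowest adjusted p = 0.696). At an unadjusted p under 0.05, 429 promoters lay above and 561 below the median promoter, where 1310 would be reached by chance. Without centring, the split around the 0 of the deposited ratios was 3356 above and 1 below. That 0 depends on a normalization not given in the sources used here, so it cannot be read as equal ChIP and input. With the replicate number as a block the centred split was 268 above and 2834 below. The block takes the spread between numbers out of the error of a group mean, so the chance count does not apply to it. Without β-catenin array 2 the split was 86 and 1200. The balance turned to 633 above and 284 below without Plakoglobin array 1, 626 and 207 without Plakoglobin array 3, 848 and 357 without the eBayes trend, 324 and 220 with robust eBayes, and 383 and 284 with single-copy accessions only.

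Some promoters with peaks in all 3 Plakoglobin arrays had high and steady ratios, and 4 of them were chosen as examples after their values were seen. Gpatch1 on chromosome 7 (start site 23744470) had 2.25 ± 0.57, Bmt2 on chromosome 6 (13433087) had 2.52 ± 0.73, Banf2 on chromosome 2 (143785080) had 1.75 ± 0.44 and P3h1, a collagen prolyl hydroxylase, on chromosome 4 (117578555) had 1.24 ± 0.27. Their β-catenin means were -0.04 ± 0.08, 0.19 ± 0.06, -0.09 ± 0.09 and 0.07 ± 0.40. The positions are those of the peak lists, whose build is not given in the sources used here. Each of the 4 had a limma adjusted p of 0.696 over input, so none passed, and their ratios are high in part because they were picked on the same arrays. The eBayes trend also gives promoters with a high mean ratio a larger modelled spread. The SE of the difference was 2.41 at Bmt2 and 1.4 at Gpatch1, against a median of 0.29 over promoters. Without the trend the lowest limma adjusted p for Plakoglobin was 0.356. Peaks in all 3 arrays did not require a high mean: the histone gene H2bc15, also chosen after its values were seen, had -0.12 ± 0.04.

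The second comparison asks the same of β-catenin. Hexim1, an inhibitor of the elongation factor P-TEFb, had the highest ratio of the fixed genes, 0.73 ± 0.90, above 0 in 3 of 3 arrays with a peak in 1. Krt10 had 0.62 ± 0.98 with a peak in 1 array, and Trp63, the master regulator of the epidermal lineage, had 0.32 ± 0.49. Ctnnb1 had 0.23 ± 0.27 and Jup 0.24 ± 0.36, both without a peak. Myc had 0.15 ± 0.13, above 0 in 3 of 3 arrays. Axin2 had -0.07 ± 0.08, Ccnd1 0.00 ± 0.13 and Krt5 -0.07 ± 0.06. In limma 0 promoters passed (lowest adjusted p = 0.894), and at an unadjusted p under 0.05, 68 lay above and 392 below the median promoter. That split turned to 1634 above and 18 below without centring, around the 0 of the deposited ratios, and to 310 and 275 without the eBayes trend. It was 254 and 872 with MAD scaling. With the replicate block, which takes the spread between numbers out of the error, it was 55 and 2414. Leaving out 1 array kept more below than above but moved the counts, from 9 and 205 without Plakoglobin array 3 to 252 and 457 without β-catenin array 1. Since 0 promoters passed, none was called with both antibodies.

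The third comparison, the aim stated in the design, sets Plakoglobin against β-catenin. The promoters with the smallest p for a higher Plakoglobin ratio belong to Xmr and its relative Gm4836, members of an X-linked multi-copy germ-line gene family. The 4 sequences of the Xmr accession averaged 1.58 with Plakoglobin and -1.18 with β-catenin, a difference of 2.76, and the 6 sequences of the Gm4836 accession averaged 1.46 and -1.20. The first start site listed is the same for both accessions (X chromosome, 25712534). Each accession had a peak in 3 of 3 Plakoglobin arrays and in 0 of 3 β-catenin arrays. Peaks were counted over all sequences of an accession, so those of different arrays may lie at different copies. Sequences of these accessions are not independent of each other, whether probes hybridised across such copies cannot be read from these ratios, and none passed (limma adjusted p = 1). 1700024B05Rik followed, with 1.01 ± 0.60 against -1.28 ± 0.52, a difference of 2.29 (SE 0.36), and no peak. On the other side stood Cyp2c37, a cytochrome P450, with a difference of -0.52 (SE 0.16), Dmxl1 with -0.45 (SE 0.15), the MHC class I gene H2-T22 with -0.73 (SE 0.25), the mitochondrial protease gene Yme1l1 with -1.03 (SE 0.36) and Thbs1, which encodes the matrix protein thrombospondin-1, with -0.96 (SE 0.35).

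None of these passed, nor did any other promoter: limma called 0 higher and 0 lower with Plakoglobin (lowest adjusted p = 1). At an unadjusted p under 0.05 with the replicate number as a block, 186 were higher and 121 lower. In the main fit 149 were higher and 42 lower, where 1310 in all would be reached by chance. Leaving out 1 array moved this balance, and turned it in the first 2 of these cases: it was 76 and 120 without β-catenin array 1, 35 and 89 without β-catenin array 2, 166 and 88 without β-catenin array 3, and 396 and 31, 283 and 55, and 398 and 38 without Plakoglobin arrays 1, 2 and 3. All 3 Plakoglobin arrays lay above all 3 β-catenin arrays at 673 promoters (2.57%) and below at 673 (2.57%), where chance gives 5% in each direction for arrays that are not paired. Among the fixed genes the difference was 0.05 (SE 0.23) for Myc, 0.01 (SE 0.15) for Axin2, 0.57 (SE 0.39) for Ccnd1, 0.54 (SE 0.59) for Jup, 0.08 (SE 0.35) for Ctnnb1, -0.78 (SE 0.47) for Krt10, -0.50 (SE 0.28) for Trp63 and -0.44 (SE 0.64) for Hexim1. It was 0.17 (SE 0.25) for Cdkn1a, which encodes the cell cycle inhibitor p21, and 0.03 (SE 0.35) for Krt14. Unadjusted limma p-values of the 14 ran from 0.115 to 0.943.

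**Figure D2:**
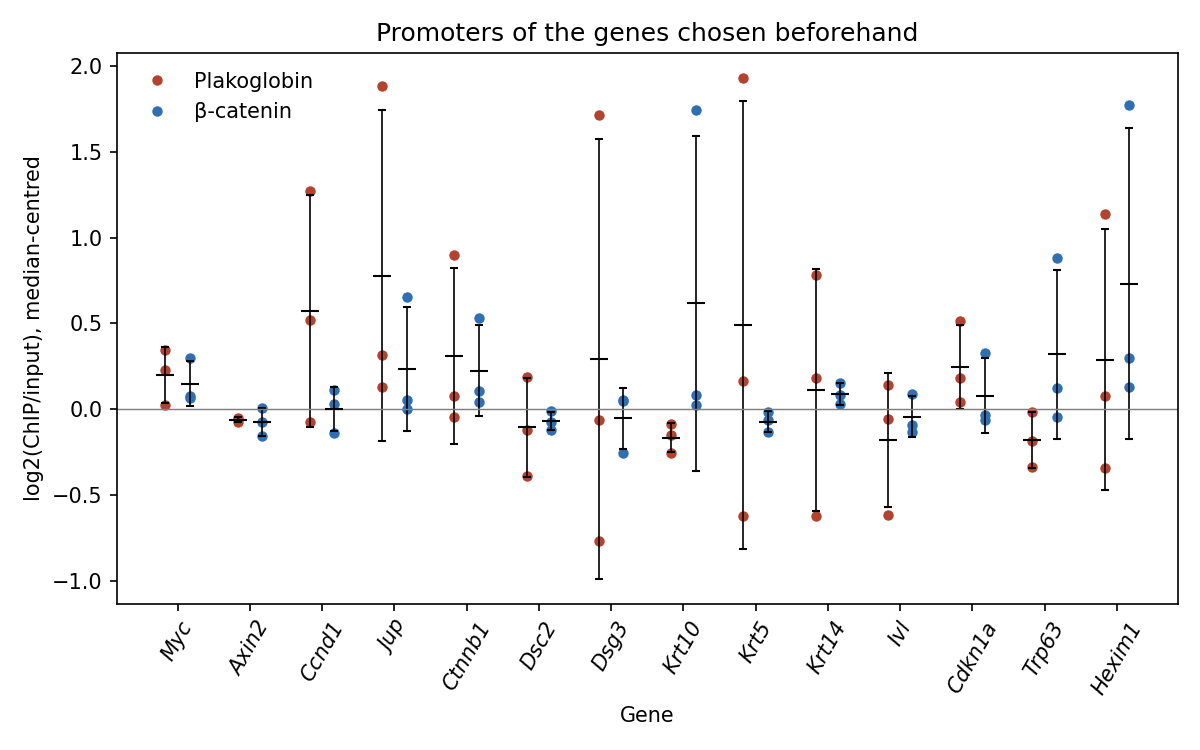
Median-centred log2 ratio of ChIP over input at the promoters of the 14 genes fixed beforehand, 1 point per array, with the mean (long bar) and SD (whiskers) over 3 arrays for Plakoglobin (red) and β-catenin (blue). A gene with several promoter sequences is shown at the one with the highest mean over all 6 arrays. Only Myc lies above 0 on all 6 arrays, and the widest spreads are those of Krt5 and Dsg3 with Plakoglobin (SD 1.31 and 1.28).

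The peak lists were compared next, to see which promoters were found repeatedly. Counts expected for independent arrays are a low bar here. Pairs of arrays that share neither antibody nor number also shared more promoters than expected, by a median ratio of 1.24. Plakoglobin peaks recurred in at least 2 of 3 arrays at 993 promoter accessions (828.5 expected if arrays were independent) and in all 3 at 95 (33.2 expected). β-catenin peaks recurred in at least 2 arrays at 160 accessions (111.3 expected) and in all 3 at 6 (1.2 expected). One peak can be listed under several accessions, so these are not independent of each other. They lay in 753 and 70 start regions for Plakoglobin and in 102 and 2 for β-catenin. The 6 β-catenin accessions, chosen after their values were seen, are 5 start sites of the Bag5 and Coa8 locus on chromosome 12 and 1 of 1700018M17Rik on chromosome 4. The β-catenin ratio was 0.92 ± 0.59 at 1700018M17Rik, 0.51 ± 0.62 and 0.40 ± 0.33 at the Coa8 start sites, and 0.08 ± 0.72, 0.86 ± 0.50 and 0.10 ± 0.25 at the Bag5 start sites. Leaving out 1 array, with peaks needed in both that remain, gave 331 to 481 accessions for Plakoglobin (331 without array 2) and 44 to 77 for β-catenin (44 without array 3). The peak lists differ in length, and with 327 top peaks from every array the order turned. At least 2 arrays then shared 27 accessions for Plakoglobin and 41 for β-catenin (20.2 and 25.1 expected). Accessions with more than 1 sequence were 2.6% of all but 19 of the 95 with Plakoglobin peaks in 3 arrays, and such accessions offer more places for a peak.

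**Figure D3:**
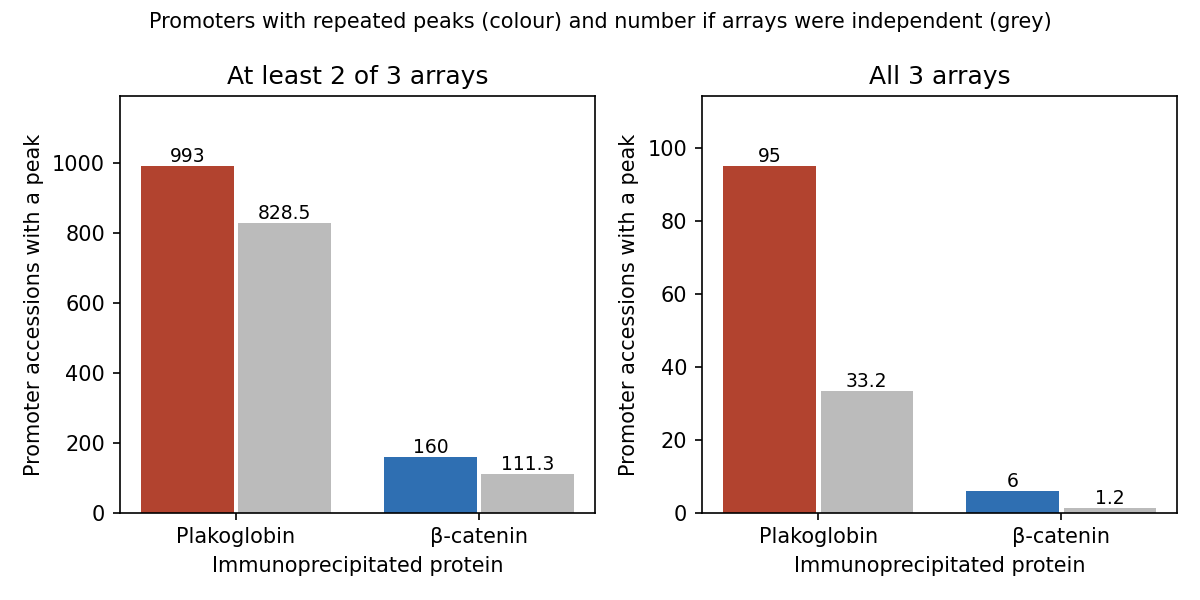
Number of promoter accessions with a peak in at least 2 of 3 arrays (left) and in all 3 (right), observed (red Plakoglobin, blue β-catenin) and calculated for independent arrays (grey). Plakoglobin reached 993 against 828.5 and 95 against 33.2, and β-catenin 160 against 111.3 and 6 against 1.2. One peak can be listed under several accessions, and these lay in 753 and 70 start regions for Plakoglobin and 102 and 2 for β-catenin.

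Both proteins had recurrent peaks at 21 accessions in 13 start regions, 2.97 times the 7.06 expected (one-sided Fisher's exact test over promoters, p = 7.9e-06; shifted promoter order, p = 0.0002). The expected count and both p-values treat the Plakoglobin and β-catenin peaks as independent, whereas arrays of the same number shared 1.65, 0.98 and 1.75 times the promoters expected for numbers 1, 2 and 3. The 10 highest of their promoter sequences belong to accessions whose first listed start site is on chromosome 2. They are those of 2210418O10Rik (start site 176665967, Plakoglobin 2.30 ± 1.49, β-catenin 1.15 ± 2.75), of LOC627905 (1.54 ± 1.56 and 1.05 ± 2.36 at its higher sequence) and 7 of the 10 sequences of Gm2026, where hybridisation across copies cannot be excluded either. β-catenin array 2 stood below 0 there (-1.81 at 2210418O10Rik) and β-catenin array 1 at 3.64. On the X chromosome, chosen after the values were seen, the promoters of Usp27x, a ubiquitin protease (start site 5664146), and Phf6, a chromatin-associated PHD-finger protein (45436508), had smaller, steadier ratios. They were 0.46 ± 0.18 and 0.51 ± 0.36 at Usp27x and 0.45 ± 0.13 and 0.31 ± 0.55 at Phf6, with Usp27x above 0 on all 6 arrays. The count of 21 was 0 without β-catenin array 1, 12 without array 2 and 9 without array 3, and 5, 10 and 12 without Plakoglobin arrays 1, 2 and 3. It was 0 with 327 top peaks from every array.

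Gene lists were tested against all other promoters, with 63 tests in all and 0 members of any list past the threshold, over all promoters or adjusted over the list alone. Of 34 Wnt pathway components, 29 lay above 0 with Plakoglobin (median 0.23) and 27 with β-catenin (0.17), and the list missed the threshold for both (camera adjusted p = 0.053 and 0.0754). Its medians were above 0 on all 6 arrays, as were those of Wnt targets and basal keratinocyte genes, which made no call. Wnt pathway members with the smallest p for the difference were Apc, part of the β-catenin destruction complex (0.30 ± 0.54 with Plakoglobin, -1.02 ± 1.17 with β-catenin), and the receptor gene Fzd1 (0.84 ± 1.37 and -0.15 ± 0.24). All 14 cell cycle exit genes lay above 0 with Plakoglobin and 13 with β-catenin (median 0.25 and 0.29; adjusted p = 0.25 and 0.0754), among them Cdkn2d at 0.65 ± 1.15 and 0.09 ± 0.20. Among named genes in general 62.0% and 57.0% lay above 0, and the unmerged unnamed promoters in the background may lower the adjusted p of the Wnt pathway and cell cycle exit lists.

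Wnt targets had 17 of 24 above 0 with each antibody (median 0.08 and 0.15; adjusted p = 0.619 and 0.201). Adherens and tight junction genes had 14 and 12 of 18 (0.16 and 0.18; 0.338 and 0.204), with the tight junction gene Cldn7 at 1.19 ± 1.22 with Plakoglobin and -0.04 ± 0.13 with β-catenin. Desmosome genes had 7 and 6 of 15 (-0.02 and -0.02; 0.749 and 0.912). Terminal differentiation genes had 11 and 12 of 23 (-0.01 and 0.06; 0.98 and 0.967). In that list Casp14, a protease of cornifying keratinocytes (1.87 ± 1.92 with Plakoglobin), and Sprr1a, a cornified envelope protein (1.02 ± 0.95), had Plakoglobin peaks in 2 of 3 arrays. Basal keratinocyte genes had 10 and 9 of 15 above 0 (0.11 and 0.27; 0.869 and 0.204). Keratin genes had 24 and 12 of 40 (0.08 and -0.09; 0.782 and 0.204), and their difference was the nearest to a call in the contrast, median 0.18, adjusted p = 0.964. Without Plakoglobin array 2 the contrast called keratin genes higher (adjusted p = 0.000915), and olfactory (5.85e-08) and vomeronasal receptors (0.000419) lower with Plakoglobin, and without β-catenin array 3 it called olfactory receptors lower (0.0249). With an estimated correlation, on all 6 arrays, the adjusted p was 0.975 for each of these 3 lists, and the left-out fits were run at the preset correlation only.

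Olfactory receptors, silent in most tissues outside the nose, made the 1 call of the 63 tests. With Plakoglobin their promoters ranked below other promoters (386 of 940 above 0, median -0.06, mean 0.04 of the other sign, camera adjusted p = 0.0294), and with β-catenin 383 were above 0 (median -0.04, adjusted p = 0.204). The list was also called lower with β-catenin under quantile normalization (0.00425), MAD scaling (0.00175) and without β-catenin array 2 (1.51e-05), but not with an estimated correlation (0.978). The Plakoglobin call was lost with an estimated correlation (adjusted p = 0.954), with the replicate number as a block (0.0561) and without Plakoglobin array 3 (0.846), and its direction turned without Plakoglobin array 1 (0.949). Array medians followed the number, not the antibody: -0.20, 0.14 and -0.21 with Plakoglobin and -0.06, 0.11 and -0.18 with β-catenin. Vomeronasal receptors had 66 and 57 of 141 above 0 (median -0.01 and -0.04; adjusted p = 0.658 and 0.292), with array medians of the same signs. This list was called lower with Plakoglobin without Plakoglobin array 2 (adjusted p = 7.56e-08) and with MAD scaling (0.0192), and with β-catenin under quantile normalization (0.0405), MAD scaling (0.0413) and without β-catenin array 2 (0.0176). With an estimated correlation, on all 6 arrays, its adjusted p was 0.954 and 0.978, and these alternatives were run at the preset correlation only.

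**Figure D4:**
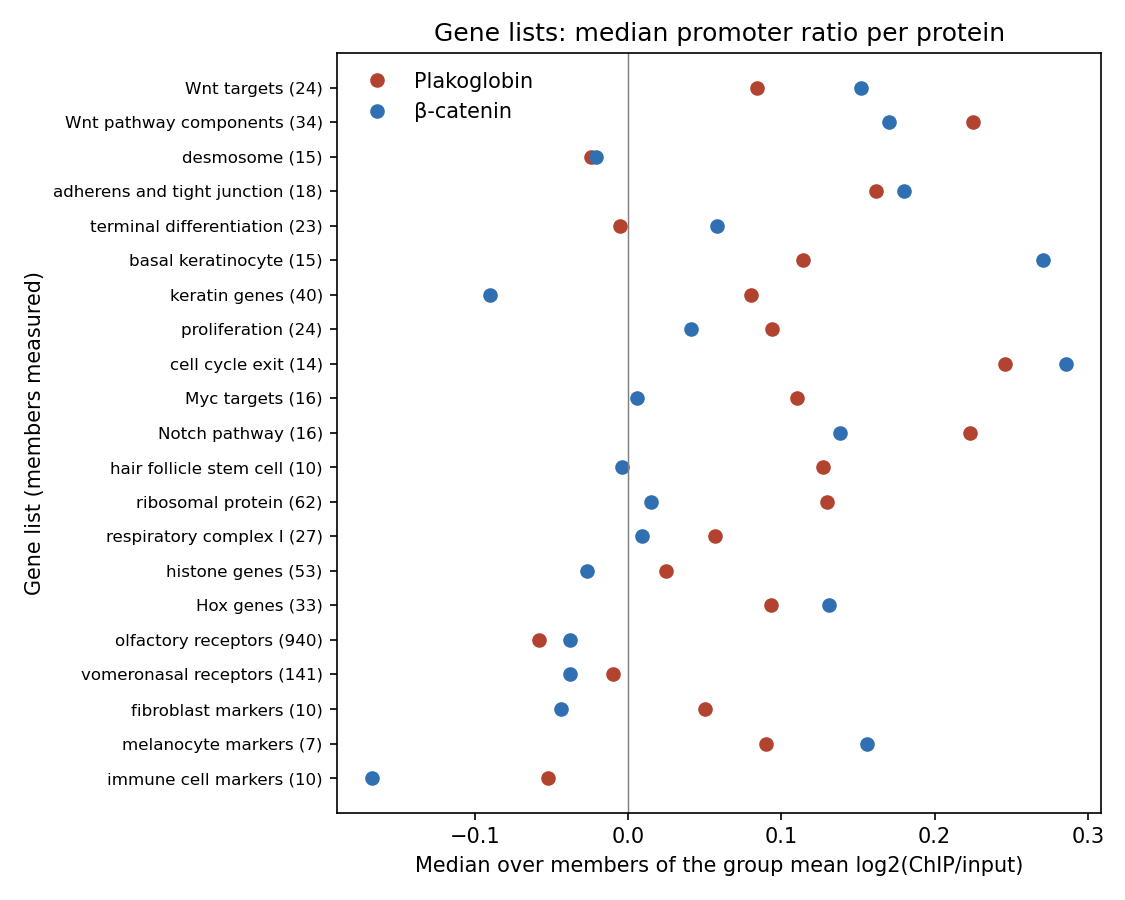
Median over list members of the mean log2 ratio of ChIP over input for Plakoglobin (red) and β-catenin (blue), with the number of measured members in brackets. Medians run from -0.17 (immune cell markers, β-catenin) to 0.29 (cell cycle exit, β-catenin), and the list test of these ratios called only the olfactory receptors with Plakoglobin, a call lost with an estimated correlation (adjusted p = 0.954).

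The remaining lists made no call with either antibody on all 6 arrays. Without Plakoglobin array 2, ribosomal proteins (adjusted p = 0.0214), Hox genes (0.0435) and proliferation (0.0481) were called higher with Plakoglobin, as were keratin genes (0.0423). With an estimated correlation, on all 6 arrays, the adjusted p was 0.954 for each of these 4 lists, and the fit without this array was run at the preset correlation only. For Plakoglobin and β-catenin in turn, members above 0 and adjusted p were 14 and 13 of 24 for proliferation (0.749 and 0.635), 10 and 8 of 16 for Myc targets (0.658 and 0.848) and 13 and 12 of 16 for the Notch pathway (0.338 and 0.204). They were 6 and 5 of 10 for hair follicle stem cell genes (0.869 and 0.967), 44 and 32 of 62 for ribosomal proteins (0.338 and 0.848) and 17 and 15 of 27 for respiratory complex I (0.869 and 0.967). Hox genes had 22 and 23 of 33 (0.749 and 0.204) and histone genes 27 and 24 of 53 (0.869 and 0.561). Markers of other skin cell types had 5 and 3 of 10 for fibroblasts (0.806 and 0.912), 5 and 5 of 7 for melanocytes (0.808 and 0.617) and 3 and 3 of 10 for immune cells (0.779 and 0.322).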

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

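Tests chosen only after the result was seen were the failed-array test, the peak counts per gene list, the counts above a log2 ratio of 1, the start-site test, the histone counts at the nearest start site without 1 array and the bootstrap requirement on the per-array histone ratios.

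Peaks on mitochondrial DNA were not singled out in the comparisons above, and they were listed on 4 of 6 arrays. Plakoglobin array 1 had 5 of 2524 peaks (0.198%, exact 95% interval 0.064 to 0.462%) and β-catenin array 3 had 5 of 1958 (0.255%, 0.083 to 0.595%), above the 3 counts that a count of 0 allows. The others had 3, 0, 1 and 0, and the intervals cover counting error only.

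Arrays of the same number correlated better than arrays of the same antibody. Input DNA shared by the arrays of a number is one candidate explanation, and in all 3 same-number pairs the lowest 1% of promoters overlapped more than the highest 1% (168, 46 and 202 shared against 25, 3 and 8, with 2.62 expected), which is consistent with it. Pairs of different number that include β-catenin array 2 showed a smaller excess of the same kind, which input shared within a number does not predict. It was 25 against 0 with β-catenin array 1, 16 against 3 with Plakoglobin array 3, 14 against 4 with β-catenin array 3 and 7 against 0 with Plakoglobin array 1. Pairs of different number without that array shared 1 to 3 of the lowest 1%, near the 2.62 expected, and most of them shared more of the highest 1%. A trend common to most promoters of an experiment may add to it, since the lowest Spearman correlation over central promoters in same-number pairs was 0.258, but Plakoglobin arrays 1 and 3 reached 0.293 and Plakoglobin array 1 with β-catenin array 3 reached 0.292. Both explanations stay open, and no biological explanation was tested.

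Strong ratios rarely recurred within an antibody: 34 promoters exceeded a log2 ratio of 1 on all 3 Plakoglobin arrays (12.1 expected) and 0 on all 3 β-catenin arrays (0.6 expected). A single failed array per antibody may contribute: the best same-antibody Pearson correlation was only 0.063, but Plakoglobin arrays 1 and 3 reached a Spearman correlation of 0.288, and array 2 had the lowest array weight with both antibodies (0.301 and 0.366). Few DNA molecules sampled before amplification could give the same picture, and accessions with at least 5 sequences correlated between arrays by only 0.009 more than those with 1 (95% bootstrap interval -0.018 to 0.039). That mean pools 0.098, 0.078 and 0.064 for the Plakoglobin pairs with -0.076, -0.030 and -0.054 for the β-catenin pairs. The interval rules out the gain of more than 0.1 that the explanation called for, but it also allows values above 0, and only 37 accessions have that many sequences, so both explanations stay open.

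Histone genes carried Plakoglobin peaks in at least 2 arrays more often than other genes: 18 of 53 (33.96%) against 4.1%, Fisher's exact test p = 2.19e-12, adjusted 4.6e-11 over the 21 lists, the only call in 42 such tests. With β-catenin it was 2 of 53, a ratio of 6.19 beside 8.28 with Plakoglobin (adjusted p = 0.448), and β-catenin array 3 alone had 20 of 53 (37.74%), a ratio of 4.11 that no single Plakoglobin array exceeded. The accessions behind the 18 genes lie in 8 start regions, and the list test on ratios made no call. One peak listed under several neighbouring start sites may account for much of it, since with only the nearest start site the share fell to 4 of 53, a ratio of 2.43 (Fisher's exact test, p = 0.0828), between the bounds set for it. Without 1 Plakoglobin array the lowest ratio was 10.68 as listed and 4.07 at the nearest start site (3 of 53 genes, Fisher's exact test p = 0.0384). This met the bound set against dependence on a single array. Such ratios need peaks in both remaining arrays, which also lowers the share of other genes, so they are not comparable with 8.28 and cannot decide it. As listed, Plakoglobin arrays 1 to 3 alone gave ratios of 4.02, 2.16 and 3.85, so more than 1 array contributed. At the nearest start site they gave 2.5, 0.95 and 2.05, and dependence on single arrays stays open there. Binding of Plakoglobin alone also stays open. The highest β-catenin ratio per array at the nearest start site (1.83) exceeded the lowest Plakoglobin one (0.95), which was set beforehand to count against it. Their quotient of 1.93, however, had a 95% bootstrap interval over genes of 0.711 to 6.42.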

How the results depend on the processing

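Alternatives added after seeing the data were the probe median, single-copy accessions, 1 bp overlap, start regions, nearest start site, all histone alternatives, and MAD scaling and no centring for the list tests. Every limma count stayed at 0 under all alternatives run, a Benjamini-Hochberg threshold of 0.1 included, with a lowest adjusted p for the difference of 0.137 (without β-catenin array 1). With the replicate block the lowest limma adjusted p was 0.89 for the difference, 0.159 for Plakoglobin and 0.202 for β-catenin. The last 2 leave the spread between numbers out of their error. Apart from the olfactory list (adjusted p = 0.0561) the block changed no other call. The 6 arrays split into 3 and 3 in 10 ways, too few for a share under 0.05. All 10 called 0 promoters at the adjusted threshold. At an unadjusted p under 0.05 the real split gave 191 and the highest other 2144, and 9 of 10 gave as many or more. The splits that part all same-number pairs gave 191, 231, 198 and 144, and those that keep a pair together gave 721 to 2144, which points to a structure by number. The 111 named promoters kept the sign of their difference in 1049 of 1110 alternative values and had the other sign in 61, with 0 past the threshold. Self-test recovery was 2% at log2 size 1, so small differences lie below what the main, unpaired fit of these arrays can show.

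List calls, 1 in the 63 tests, were 0 with an estimated correlation, with fry and with the replicate block, 4 with quantile normalization, 3 with the mean of a gene's promoters, 4 with the probe median and 5 with MAD scaling, and 0 to 10 leaving out 1 array (10 without Plakoglobin array 2). The olfactory adjusted p ran from 8.01e-14 to 0.954 and turned direction without Plakoglobin array 1 (0.949). Wnt pathway components with Plakoglobin passed with quantile normalization (adjusted p = 0.036), MAD scaling (0.014), the probe median (0.00378) and without Plakoglobin array 2 (0.0223) or β-catenin array 2 (0.0197). The range went up to 0.954, the adjusted p with an estimated correlation. With β-catenin, Wnt pathway components and cell cycle exit passed with the mean of a gene's promoters (both 0.0472), the probe median (both 0.0152) and without Plakoglobin array 3 (0.0498 and 0.0104), against 0.925 and 0.834 with an estimated correlation. Counts of Plakoglobin, β-catenin and shared recurrent promoters (993, 160 and 21) were 560, 51 and 5 at a peak false discovery rate up to 0.05, 27, 41 and 0 with 327 top peaks per array, 394, 79 and 5 with overlap of 50% of the smaller peak, 515, 96 and 11 with 1 bp, 95, 6 and 0 in 3 of 3 arrays, and 6759, 3014 and 1149 in 1 of 3. Start regions gave 102 for β-catenin and 13 shared, and the nearest start site 105 for β-catenin. Leaving out 1 array of the antibody counted gave 331 to 481, 44 to 77 and 0 to 12. The 18 histone genes became 4 with the nearest start site (3 to 4 there leaving out 1 array), 0 with equal top peaks, 7 in 3 of 3 arrays and 9 to 12 leaving out 1 array. Stricter rules and fewer arrays remove peaks by construction, and otherwise the cause was not tested.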

Other observations

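More promoters kept one sign on all 6 arrays than independent arrays would give, a count made after seeing the data: 1832 were above 0 on every array (405 expected) and 1356 at or below 0 (414 expected). Promoters above 0 on all Plakoglobin arrays and at or below 0 on all β-catenin arrays numbered 146 (410 expected), and the reverse 147 (409 expected). These expectations ignore that arrays of the same number correlate, which on its own raises the first 2 counts and lowers the last 2. Myc was among the first kind, with 0.20 ± 0.16 and 0.15 ± 0.13.

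Peak overlap between arrays was compared for all 15 pairs, also after seeing the data. The ratio of shared to expected promoters had a median of 1.4 for the 6 pairs of one antibody (5 passed a Benjamini-Hochberg adjusted shift test), 1.65 for the 3 pairs of one number (2 passed) and 1.24 for the 6 pairs that share neither (4 passed). The highest was 3.4, between β-catenin arrays 1 and 2 (44 shared, 13.0 expected, permutation p by shifts = 0.0001, the smallest that 10000 shifts can give), and the lowest 0.98, between Plakoglobin and β-catenin array 2.

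Respiratory complex I genes had Plakoglobin peaks in at least 2 arrays at 4 of 27 (14.81% against 4.19% of other genes, Fisher's exact test p = 0.0252, adjusted p = 0.176), namely Ndufa1, Ndufa7, Ndufaf5 and Ndufb5, chosen after their values were seen, and the list did not pass.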
